A study of Mus musculus with 18 samples.

How the data were processed

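RNA-seq was used to measure transcripts in mouse hearts after sham surgery or myocardial infarction (MI). Per the labels, newborn mice received an adeno-associated virus of serotype 9 under the skin. The virus carried mouse Fgf17, a secreted fibroblast growth factor, or was a control vector. At 8 weeks of age, MI was made by permanently tying the left anterior descending coronary artery, and sham surgery left the artery open. The 18 libraries fall into 5 groups: sham with 4 libraries, MI day 3 with the control vector with 4, MI day 3 with FGF17 with 4, MI day 14 with the control vector with 3, and MI day 14 with FGF17 with 3. The labels name 1 sham group without a day and do not state whether the libraries of a group came from separate animals. No sham group received the Fgf17 vector.

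The deposited table holds FPKM values (fragments scaled to transcript length and to the mapped fragments of the library) for 12988 genes, and the authors describe Trizol extraction, Illumina libraries, read checks with FastQC 0.11.7, trimming with cutadapt 1.17, alignment with HISAT2 2.1.0 to the GRCm38 mouse genome and quantification with StringTie 1.3.3. FPKM corrects for gene length and for the total mapped fragments of a library. It does not correct for a few abundant genes taking a different share of the fragments, so the scaling between libraries was varied. The table lists few low genes: 12980 of 12988 genes reach a mean of at least 0.5 FPKM in at least 1 group, and 12495 are above 0 in every library. The authors' read totals were not used here, and whole read counts could not be recovered from the FPKM values, so the depth of each library is unknown and no counting intervals are given. The sum of FPKM over the table ranged from 301085 to 362004 per library. Each column was assigned to its group by its name, and libraries carry the numbers of the column names, which differ from the numbers in the sample titles. The day 3 columns of the FGF17 group give the vector in short form, and Fgf17 levels were not used to assign any column.

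Values were analysed as log2(FPKM + 0.5). Genes with at least 1 FPKM in at least 3 libraries were tested, 12052 in all. Fold changes on this scale understate the change of genes with low FPKM. limma 3.58.1 in R 4.3.3 fitted 5 group means to the 18 libraries in 1 model (lmFit, contrasts.fit, eBayes with a mean-variance trend), and 6 contrasts were taken: MI against sham at each day, FGF17 against the control vector at each day after MI, day 14 against day 3 after MI, and the difference between the FGF17 effects at the 2 days. The p-values were adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05, and are two-sided. They measure the spread between libraries within groups, taken as 1 value per gene over the 5 groups, part of which may be technical. Changes are given as log2 change ± standard error from this model, and levels as mean FPKM ± SD. Fgf17 was also compared by an exact two-sided permutation test.

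For each contrast the named genes followed a rule fixed before the data were examined. Candidates needed a mean of at least 5 FPKM in a compared group and no overlap of libraries. The overlap condition was not asked of the difference between the days. Genes with provisional symbols and immunoglobulin or T cell receptor segments were left out. Of the candidates past the threshold, the 8 largest rises and the 8 largest falls were taken. A constant set of 21 genes of FGF signalling, cardiac stress, contraction, matrix, inflammation and metabolism was added, and the members with the smallest p of each gene list. Of the constant set, Etv4 did not pass the filter on low values. The 40 gene lists were fixed at the same time: 21 of cell programmes, 16 of cell type markers and 3 of sample quality. The 37 with at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast. The lists of B cell, lung epithelial and thymus markers had fewer tested members and were not tested. Camera asks whether the genes of a list moved further in 1 direction than the other genes. Members past the threshold were counted over all genes tested and adjusted over the list alone. List members whose symbol stands for several entries of the table (13 symbols, 27 entries) were left out, a choice made after the table was seen. The correlation across genes between FGF17 and MI effects was computed for pairs of contrasts that share no library.

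Alternatives chosen in advance were a pseudocount of 0.1 or 1, no filter or a filter at 5 FPKM, median-of-ratios scaling, rescaling to a total of 1000000, a fit of only the groups compared, robust eBayes, the library number as a block, and leaving out each library in turn. For the lists they were an estimated correlation and fry, another test in limma. After seeing the data, 2 more were added: leaving the 13 mitochondrially encoded genes out before rescaling, and leaving out the 2 libraries with the lowest mitochondrially encoded share in their groups. The model was tested on simulated data with 200 of 12052 genes changed by 1.5, 2 or 4 times. At 2 times, it called 95.5% of the changed genes with the group sizes of MI day 3 against sham, 91.0% with those of FGF17 at day 3 and 92.5% with those of FGF17 at day 14. At 1.5 times, these shares were 55.2%, 65.7% and 58.2%. False calls made up 6.29%, 6.04% and 4.62% of all calls in these 3 contrasts. The changed genes were not drawn from those of low level. Each gene had the same spread in every group, independent of other genes. The shares may therefore be too high for groups with a larger spread. Numerical work also used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.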

Results

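Heart transcript levels were measured by RNA-seq in 18 libraries: 4 of sham hearts, 4 at day 3 and 3 at day 14 after MI with the control vector, and 4 at day 3 and 3 at day 14 after MI with adeno-associated virus 9 carrying Fgf17. The day at which sham hearts were taken is not given, so both MI days were compared with the same sham group. Depth is unknown, since the values are FPKM. Transcripts of the 13 protein-coding genes of the mitochondrial genome made up 37.9% ± 2.73 of the summed FPKM in sham (SD, n = 4), 25.9% ± 4.72 in MI day 3 with the control vector (n = 4), 29.1% ± 1.19 in MI day 3 with FGF17 (n = 4), 30.5% ± 3.99 in MI day 14 with the control vector (n = 3) and 27.5% ± 6.12 in MI day 14 with FGF17 (n = 3). The lowest shares within these groups were 18.8% in MI day 3 control library 4 and 20.8% in MI day 14 FGF17 library 4. Pearson's r of log2 values across genes was 0.968 to 0.986 between libraries of 1 group and 0.873 to 0.982 between libraries of different groups.

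**Figure D1:**
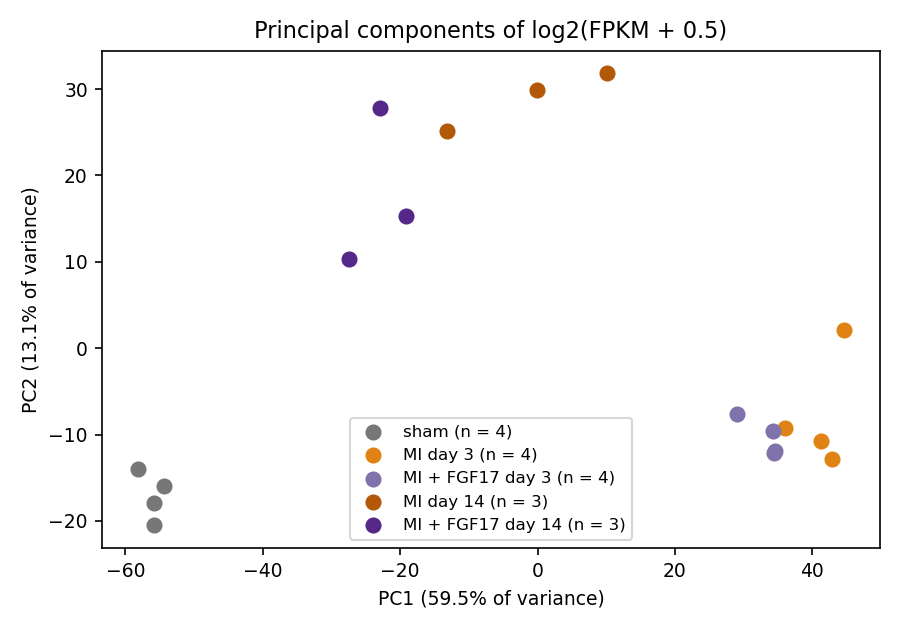
Each point is 1 of the 18 libraries on the first 2 principal components of the log2(FPKM + 0.5) values, which carry 59.5% and 13.1% of the variance. Sham libraries lie between -58.2 and -54.3 on component 1, MI day 3 control libraries between 36.0 and 44.7, MI day 3 FGF17 libraries between 29.0 and 34.6, MI day 14 control libraries between -13.1 and 10.1, and MI day 14 FGF17 libraries between -27.5 and -19.2.

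The first question was whether the vector raised Fgf17 in the heart. Fgf17 (ENSMUSG00000022101.6, chromosome 14, 70636203 to 70642268, minus strand in GRCm38) was listed at 0 in the 4 sham libraries. At day 3 after MI its level was 58.9 ± 12.1 FPKM with the Fgf17 vector (SD, n = 4) and 0.132 ± 0.169 with the control vector (n = 4), a log2 change of 6.57 ± 0.22 (adjusted p = 5.37e-12). The exact two-sided permutation p was 0.0286, the smallest that 4 against 4 libraries allow. At day 14 the levels were 62.8 ± 26.6 FPKM (n = 3) and 0.0848 ± 0.147 (n = 3), a log2 change of 6.71 ± 0.25 (adjusted p = 4.07e-11). The exact permutation p was 0.1, the smallest that 3 against 3 libraries allow. All libraries with the Fgf17 vector had more Fgf17 than any control library of their day.

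The comparison of MI day 3 with sham, both with the control vector, addresses the early response to infarction. Of the planned lists, 24 of 27 matrix genes other than collagens and 19 of 19 macrophage markers rose, and 25 of 27 fatty acid oxidation genes fell (n = 4 and 4). With an estimated correlation these lists had adjusted p = 0.211, 0.0827 and 0.0747. Spp1, the matricellular protein osteopontin (ENSMUSG00000029304.14, chromosome 5, 104435118 to 104441050, plus strand), rose from 2.48 ± 1.07 to 662 ± 87.0 FPKM (log2 change 7.85 ± 0.24, adjusted p = 3.84e-13). Arg1, an arginase of macrophages, rose from 0.0865 ± 0.103 to 129 ± 19.3 FPKM (7.80 ± 0.38 log2). Sprr1a, a small protein induced in stressed cardiomyocytes, rose by 7.50 ± 0.33 log2, the matrix protein gene Tnc by 6.04 ± 0.14, Cthrc1 of activated fibroblasts by 5.88 ± 0.19 and the acute phase gene Saa3 by 5.37 ± 0.55. Apoc2, an apolipoprotein gene, was listed at 0 in sham and reached 15.7 ± 5.39 FPKM. Timp1, an inhibitor of matrix proteases, rose from 5.61 ± 1.20 to 324 ± 33.9 FPKM. The cytochrome P450 gene Cyp1a1 fell from 13.3 ± 4.30 to 0.872 ± 0.593 FPKM (-3.39 ± 0.38 log2). Inmt, Slc26a10 and Lgals4 fell, with log2 changes of -2.55 ± 0.37, -2.07 ± 0.15 and -1.82 ± 0.25. Pnpla2, the triglyceride lipase ATGL, fell from 141 ± 12.1 to 42.4 ± 6.52 FPKM, and G0s2, its inhibitor, changed by -2.06 ± 0.20 log2 (adjusted p = 1.26e-07).

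At day 3, 17 of 17 collagen genes rose (17 adjusted over the list alone), with log2 changes of 4.95 ± 0.18 for Col1a1 and 4.79 ± 0.18 for Col3a1, and a list median of 2.23. The collagen list had camera adjusted p = 1.14e-08, and adjusted p = 0.211 with an estimated correlation. Of 27 matrix glycoprotein, crosslinking and protease genes, 24 rose (24 adjusted over the list alone), among them Postn by 4.23 ± 0.24 log2. The other matrix list had camera adjusted p = 1.14e-08, and adjusted p = 0.211 with an estimated correlation. All 27 cell cycle genes rose, and as many adjusted over the list alone, by a median of 3.36 log2, and Mki67, a marker of cycling cells, went from 0.147 ± 0.0532 to 11.9 ± 1.19 FPKM. The cell cycle list had camera adjusted p = 5.66e-16, and adjusted p = 0.0877 with an estimated correlation. All 19 monocyte and macrophage markers rose by a median of 2.51 log2, with 2.51 ± 0.12 for Lyz2 (19 adjusted over the list alone). The macrophage list had camera adjusted p = 2.86e-10, and adjusted p = 0.0827 with an estimated correlation. Of 12 neutrophil markers 10 rose (11 adjusted over the list alone), with 3.67 ± 0.42 for S100a8. The neutrophil list had camera adjusted p = 0.00230, and adjusted p = 0.339 with an estimated correlation. All 19 inflammatory cytokine genes and all 20 interferon-stimulated genes rose, with the same counts adjusted over the list alone (camera adjusted p = 1.32e-05 and 6.09e-05). With an estimated correlation, these had adjusted p = 0.211 and 0.286. The 8 erythroid markers also rose (8 adjusted over the list alone), by a median of 2.72 log2. The erythroid list had camera adjusted p = 0.00550, and adjusted p = 0.366 with an estimated correlation.

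Genes of mitochondrial energy metabolism fell at day 3: 25 of 27 fatty acid oxidation genes, 19 of 20 tricarboxylic acid cycle genes, 35 of 36 nuclear genes of respiratory complex I and 30 of 31 of complexes III, IV and ATP synthase, with the same counts adjusted over the list alone. Their medians were -0.96, -0.61, -0.58 and -0.53 log2, and camera gave adjusted p = 1.05e-19, 5.98e-15, 6.69e-19 and 3.24e-17. With an estimated correlation the first 3 lists had adjusted p = 0.0747 and the last had adjusted p = 0.0827. Cpt1b, the muscle enzyme for fatty acid entry into mitochondria, changed by -1.11 ± 0.14 log2 (adjusted p = 2.39e-06). Ppargc1a, the coactivator PGC-1alpha, fell to 16.7 ± 4.75 FPKM (adjusted p = 0.00255), and 11 of 18 mitochondrial biogenesis and dynamics genes fell (11 adjusted over the list alone). The mitochondrial biogenesis list had camera adjusted p = 3.90e-07, and adjusted p = 0.0116 with an estimated correlation. The mitochondrially encoded genes moved with them: 11 of 13 fell (11 adjusted over the list alone), with a median of -0.67 log2. The mitochondrially encoded list had camera adjusted p = 1.78e-05, and adjusted p = 0.273 with an estimated correlation. Of 18 sarcomere genes 14 fell (14 adjusted over the list alone), among them Myh6, the adult alpha myosin heavy chain, from 1759 ± 212 to 972 ± 109 FPKM. The sarcomere list had camera adjusted p = 1.40e-09, and adjusted p = 0.0959 with an estimated correlation. Of 20 calcium handling and ion channel genes 10 fell (10 adjusted over the list alone), and the calcium pump gene Atp2a2 changed by -0.61 ± 0.092 log2. The calcium handling list had camera adjusted p = 3.90e-07, and adjusted p = 0.123 with an estimated correlation. Myh7, the fetal beta myosin, changed by -1.23 ± 0.32 log2 (adjusted p = 0.00304). The natriuretic peptide gene Nppa rose by 0.46 ± 0.16 log2 (adjusted p = 0.0213, but 0.438 with median-of-ratios scaling, and 0.0860, 0.0830 and 0.0585 without sham library 4, MI day 3 control library 2 or library 4), and Nppb changed by 0.10 ± 0.22 (adjusted p = 0.706), with a negative sign under that scaling. Atrial markers, a list that holds Nppa, rose in 1 and fell in 4 of 9 cases (1 and 4 adjusted over the list alone). The atrial list had camera adjusted p = 0.0204, and adjusted p = 0.339 with an estimated correlation. Of 16 FGF feedback genes 10 rose (10 adjusted over the list alone, 7 rising and 2 falling over all genes with median-of-ratios scaling, camera adjusted p = 0.195), with 1.11 ± 0.16 log2 for Dusp6 and 0.78 ± 0.10 for Etv5. Spry2 and Spry4 changed by 0.37 ± 0.11 and 0.45 ± 0.13 (adjusted p = 0.00618 and 0.00512), and both lost the call with median-of-ratios scaling and with mitochondrially encoded genes left out. The heme oxygenase gene Hmox1 rose by 4.28 ± 0.18 log2.

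In all, 7337 of 12052 genes passed the threshold at day 3, 5535 higher and 1802 lower (75.4% higher). The up and down split moved with the scaling: median-of-ratios scaling gave 3609 higher and 3602 lower, and leaving out mitochondrially encoded genes gave 4210 higher and 2836 lower, as the median of all genes went from 0.25 to -0.013 and 0.087 log2. Of the genes past the threshold, 226 had the opposite sign with median-of-ratios scaling.

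The comparison of MI day 14 with sham addresses the scar stage (n = 3 and 4). Cthrc1 rose from 0.205 ± 0.210 to 30.4 ± 7.84 FPKM (log2 change 5.47 ± 0.21, adjusted p = 5.06e-11), the secreted protein gene C1qtnf3 from 0.0122 ± 0.0243 to 18.8 ± 3.01 FPKM (5.22 ± 0.25), and Comp, a cartilage matrix protein, from 2.80 ± 0.447 to 78.9 ± 7.87 FPKM (4.59 ± 0.38). Postn, the matricellular protein periostin of activated fibroblasts (ENSMUSG00000027750.16, chromosome 3, 54361109 to 54391037, plus strand), rose from 6.10 ± 1.43 to 146 ± 38.7 FPKM. Sfrp2, Ltbp2 and Emp1 rose by log2 changes of 4.96 ± 0.28, 4.16 ± 0.32 and 4.25 ± 0.65. Cyp1a1 was again lower, at 1.20 ± 0.698 FPKM against 13.3 ± 4.30. The acyl-CoA thioesterase gene Acot2 fell from 51.8 ± 2.34 to 15.0 ± 2.27 FPKM, its near-identical neighbour Acot1 changed by -1.97 ± 0.25 log2, and reads of these 2 genes may be shared. The muscle fructose bisphosphatase gene Fbp2, G0s2, Inmt and Mid1ip1 fell, with log2 changes of -1.78 ± 0.21, -1.81 ± 0.22, -2.08 ± 0.40 and -2.11 ± 0.52.

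At day 14, 17 of 17 collagen genes and 26 of 27 other matrix genes rose (17 and 26 adjusted over the list alone), by medians of 2.78 and 2.82 log2, with 3.99 ± 0.20 for Col1a1, 4.37 ± 0.19 for Col3a1 and 3.04 ± 0.25 for Timp1. Camera gave adjusted p = 2.54e-14 and 6.09e-18, and with an estimated correlation adjusted p = 0.0878 and 0.0704. Of 14 fibroblast markers 12 rose (12 adjusted over the list alone), and 17 of 18 TGF-beta and myofibroblast genes rose (18 adjusted over the list alone). The fibroblast list had camera adjusted p = 2.33e-07, and adjusted p = 0.0704 with an estimated correlation. The TGF-beta and myofibroblast list had camera adjusted p = 1.56e-06, and adjusted p = 0.139 with an estimated correlation. Of 27 cell cycle genes 25 rose by a median of 1.32 log2 (25 adjusted over the list alone), with 2.26 ± 0.16 for Mki67. The cell cycle list had camera adjusted p = 1.20e-09, and adjusted p = 0.144 with an estimated correlation. All 19 monocyte and macrophage markers rose (19 adjusted over the list alone), with 1.78 ± 0.13 log2 for Lyz2. The macrophage list had camera adjusted p = 5.43e-10, and adjusted p = 0.0704 with an estimated correlation. Of 12 neutrophil markers 2 passed the threshold (0 adjusted over the list alone, 3 at an unadjusted p under 0.05, camera adjusted p = 0.731), and S100a8 changed by 0.54 ± 0.45 log2 (adjusted p = 0.338). Interferon-stimulated genes rose in 19 of 20 cases (20 adjusted over the list alone). The interferon-stimulated list had camera adjusted p = 5.77e-05, and adjusted p = 0.317 with an estimated correlation.

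Energy metabolism genes were lower at day 14 too: 23 of 27 fatty acid oxidation genes fell (23 lower and 1 higher adjusted over the list alone), 18 of 20 tricarboxylic acid cycle genes (19 adjusted over the list alone), 19 of 36 complex I genes (21 adjusted over the list alone) and 24 of 31 genes of complexes III, IV and ATP synthase (24 adjusted over the list alone). The medians were -0.79, -0.48, -0.29 and -0.33 log2, and camera gave adjusted p = 2.14e-23, 3.35e-16, 7.22e-15 and 4.72e-15. With an estimated correlation, each had adjusted p = 0.0704. Of the mitochondrially encoded genes, 5 of 13 fell (3 adjusted over the list alone). The mitochondrially encoded list had camera adjusted p = 1.24e-04, and adjusted p = 0.354 with an estimated correlation. Mitochondrial biogenesis and dynamics genes fell in 9 of 18 cases (9 adjusted over the list alone). The mitochondrial biogenesis list had camera adjusted p = 9.30e-08, and adjusted p = 0.00770 with an estimated correlation. Sarcomere genes fell in 10 of 18 cases (10 adjusted over the list alone), with -0.57 ± 0.15 log2 for Myh6, while Myh7 changed by -0.81 ± 0.35 (adjusted p = 0.0605). The sarcomere list had camera adjusted p = 2.31e-08, and adjusted p = 0.0954 with an estimated correlation. Nppa rose from 1656 ± 306 to 3083 ± 505 FPKM (log2 change 0.90 ± 0.18, adjusted p = 4.52e-04), and of 9 atrial markers, a list that holds Nppa, 4 rose (3 adjusted over the list alone, 2 over all genes with median-of-ratios scaling, camera adjusted p = 0.881). In all, 6025 genes passed the threshold, 4940 higher and 1085 lower, against 2947 higher and 2693 lower with median-of-ratios scaling, where the median of all genes went from 0.25 to 0.011 log2 and 85 of these genes had the opposite sign.

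Between day 3 and day 14 after MI, both with the control vector, 17 of 19 cytokine genes fell (n = 4 and 3; adjusted p = 0.118 for the list with an estimated correlation). Arg1 fell from 129 ± 19.3 to 3.07 ± 2.80 FPKM (log2 change -5.45 ± 0.41, adjusted p = 5.90e-08), Spp1 from 662 ± 87.0 to 33.9 ± 14.7 FPKM (-4.34 ± 0.26) and Ccl2, a chemokine for monocytes, from 58.7 ± 5.80 to 4.31 ± 1.44 FPKM (-3.66 ± 0.21). The macrophage gene Chil3, the neutrophil gene S100a9 and the chemokine genes Cxcl5 and Ccl7 fell, with log2 changes of -4.55 ± 0.51, -3.56 ± 0.61, -3.88 ± 0.35 and -3.71 ± 0.32. Sprr1a, Timp1 and Hmox1 fell, with log2 changes of -3.62 ± 0.36, -2.71 ± 0.25 and -3.44 ± 0.19. C1qtnf3 and Comp rose by 4.67 ± 0.25 and 4.31 ± 0.38 log2, the collagen-binding proteoglycan gene Fmod by 3.42 ± 0.33, the elastin gene Eln by 2.76 ± 0.31, Col8a2 by 2.74 ± 0.33 and Angptl7 by 3.59 ± 0.37. Col1a1 changed by -0.96 ± 0.20 log2 (adjusted p = 0.00136), Col3a1 and Postn did not pass (-0.42 ± 0.19 and 0.23 ± 0.26; adjusted p = 0.109 and 0.548), and of 17 collagen genes 5 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.195). Of 27 other matrix genes 12 rose and 6 fell (12 and 6 adjusted over the list alone), by a median of 0.31 log2, and the camera call was lost with the library number as a block. The other matrix list had camera adjusted p = 0.0358, and adjusted p = 0.717 with an estimated correlation.

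All 27 cell cycle genes fell between the days (27 adjusted over the list alone), by a median of -1.97 log2, and Mki67 from 11.9 ± 1.19 to 2.65 ± 0.732 FPKM. The cell cycle list had camera adjusted p = 4.10e-27, and adjusted p = 0.0538 with an estimated correlation. Of 19 cytokine genes 17 fell, of 12 neutrophil markers 10, of 19 macrophage markers 14 and of 8 erythroid markers 8, with the same counts adjusted over the list alone. Camera gave adjusted p = 2.18e-10, 4.87e-07, 4.62e-08 and 4.99e-04 for these lists, and with an estimated correlation adjusted p = 0.118, 0.196, 0.146 and 0.370. Endothelial markers rose in 11 of 15 cases and pericyte and smooth muscle markers in 8 of 10 (11 and 10 adjusted over the list alone, camera adjusted p = 6.38e-06 and 2.70e-06; adjusted p = 0.142 and 0.118 with an estimated correlation). Fibroblast markers rose in 9 and fell in 1 of 14 cases (10 and 2 adjusted over the list alone), and complex I genes rose in 15 of 36 (15 adjusted over the list alone, and 24 over all genes without both libraries of low mitochondrially encoded share). The fibroblast list had camera adjusted p = 6.27e-05, and adjusted p = 0.179 with an estimated correlation. The complex I list had camera adjusted p = 7.96e-07, and adjusted p = 0.284 with an estimated correlation. Tricarboxylic acid cycle genes rose in 3 of 20 and genes of complexes III, IV and ATP synthase in 6 of 31 cases (3 and 5 adjusted over the list alone, and 5 and 12 over all genes without both of those libraries). The tricarboxylic acid cycle list had camera adjusted p = 0.00369, and adjusted p = 0.445 with an estimated correlation. The complex III, IV and ATP synthase list had camera adjusted p = 7.89e-05, and adjusted p = 0.413 with an estimated correlation. Of 27 fatty acid oxidation and 18 mitochondrial biogenesis and dynamics genes, 0 and 0 passed by limma (0 and 0 adjusted over the list alone, 4 and 3 higher at an unadjusted p under 0.05, camera adjusted p = 0.00893 and 0.0944; adjusted p = 0.598 and 0.314 with an estimated correlation). Atrial markers rose in 2 of 9 cases (2 adjusted over the list alone). The atrial list had camera adjusted p = 0.00394, and adjusted p = 0.316 with an estimated correlation. Of 7 skeletal muscle markers 5 rose (5 adjusted over the list alone), and the mean log2 value of the list was 2.60 to 2.86 in the 3 MI day 14 control libraries and 1.25 to 1.98 in all other libraries. The skeletal muscle list had camera adjusted p = 1.03e-04, and adjusted p = 0.0310 with an estimated correlation. In all, 3555 genes passed the threshold, 1347 higher and 2208 lower at day 14, against 2005 higher and 1722 lower with mitochondrially encoded genes left out before rescaling.

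FGF17 was compared with the control vector at day 3 after MI (n = 4 and 4). The vector was given to newborn mice, and no sham group received the Fgf17 vector. Differences present before MI therefore cannot be told apart from effects that arose after it. Apart from Fgf17, 5 of 20 interferon-stimulated and 2 of 8 erythroid genes fell. Each of these lists had adjusted p = 0.0551 with an estimated correlation. Apol11b, of the apolipoprotein L family (ENSMUSG00000091694.8, chromosome 15, 77633951 to 77643286, minus strand), fell from 14.6 ± 6.22 to 1.02 ± 0.348 FPKM (log2 change -3.24 ± 0.36, adjusted p = 5.40e-04). Rsad2, the antiviral protein viperin (ENSMUSG00000020641.16, chromosome 12, 26442746 to 26456452, minus strand), fell from 25.9 ± 5.24 to 11.8 ± 1.58 FPKM (-1.09 ± 0.16, adjusted p = 0.00838), and Isg15, a ubiquitin-like interferon-induced protein (ENSMUSG00000035692.6, chromosome 4, 156199424 to 156200818, minus strand), from 52.5 ± 19.6 to 22.7 ± 3.86 FPKM (adjusted p = 0.0435). The carbonic anhydrase gene Car2 fell, with a log2 change of -1.40 ± 0.19 (adjusted p = 0.00611). Ppargc1a rose from 16.7 ± 4.75 to 41.4 ± 10.8 FPKM (adjusted p = 0.0435), and Tmem100 and Dusp18 rose by 0.88 ± 0.15 and 0.67 ± 0.11 log2. Apol11b and the histocompatibility gene H2-Q6 (-1.35 ± 0.20 log2) have close relatives in the genome, as have Oas1a, Saa3 and the globin genes, so reads may be shared between copies.

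Of 20 interferon-stimulated genes, 5 fell over all genes and 18 adjusted over the list alone, by a median of -0.59 log2. The interferon-stimulated list had camera adjusted p = 9.30e-26, and adjusted p = 0.0551 with an estimated correlation. Among them were Isg15 with -1.13 ± 0.22 log2, Oas1a with -0.88 ± 0.15, Ifi44 with -0.86 ± 0.17 and Ddx58, the RNA sensor RIG-I, with -0.49 ± 0.080, and Isg20 fell by 1.27 ± 0.22 log2. The count of interferon-stimulated genes over all genes was 3 with median-of-ratios scaling, 1 with only these 8 libraries fitted and 2 without both libraries of low mitochondrially encoded share. Of 8 erythroid markers 2 fell over all genes and 8 adjusted over the list alone, by a median of -1.75 log2. The erythroid list had camera adjusted p = 3.56e-18, and adjusted p = 0.0551 with an estimated correlation. With only these 8 libraries fitted, 7 fell over all genes. The band 3 gene Slc4a1 changed by -1.60 ± 0.24 log2 (adjusted p = 0.00838), the red cell enzyme gene Bpgm went from 52.2 ± 16.8 to 16.3 ± 3.11 FPKM (adjusted p = 0.0163), Fam46c changed by -1.66 ± 0.28 (adjusted p = 0.0163) and the globin gene Hbb-bs had 7619 ± 2053 and 2365 ± 607 FPKM (adjusted p = 0.0540). Camera called the 27 fatty acid oxidation genes higher by a median of 0.20 log2 with 0 members past the threshold by limma (1 adjusted over the list alone, 14 at an unadjusted p under 0.05, adjusted p = 9.63e-14; adjusted p = 0.177 with an estimated correlation). It also called the tricarboxylic acid cycle, complex I and complex III, IV and ATP synthase lists higher (adjusted p = 1.41e-09, 7.31e-10 and 1.30e-09; adjusted p = 0.177, 0.209 and 0.247 with an estimated correlation), with 0 members past the threshold by limma or adjusted over the list alone and 5, 5 and 6 at an unadjusted p under 0.05. It called the 19 macrophage markers lower with a median of -0.31 log2 and 0 members past it (2 adjusted over the list alone, 10 at an unadjusted p under 0.05, adjusted p = 8.00e-08; adjusted p = 0.177 with an estimated correlation), and Adgre1, a macrophage surface receptor, changed by -0.38 ± 0.12 log2 (adjusted p = 0.259). The 7 adipocyte markers had a median of -1.20 log2, with 0 past the threshold over all genes and 6 lower and 1 higher adjusted over the list alone (6 lower at an unadjusted p under 0.05), and Retn, the hormone resistin, changed by -1.33 ± 0.29 log2 (adjusted p = 0.0681). The adipocyte list had camera adjusted p = 1.44e-04, and adjusted p = 0.308 with an estimated correlation. The adipocyte median was -0.81 without both libraries of low mitochondrially encoded share. The 13 mitochondrially encoded genes had a median of 0.20 log2, with 0 past the threshold by limma, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05. The mitochondrially encoded list had camera adjusted p = 0.0102, and adjusted p = 0.574 with an estimated correlation.

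Collagen, other matrix and cell cycle genes had medians of -0.17, -0.12 and -0.10 log2 with FGF17 at day 3, with 0 members of these lists past the threshold by limma and 0 adjusted over the list alone, and 0, 1 and 0 lower at an unadjusted p under 0.05 (camera adjusted p = 0.0887, 0.189 and 0.139). Col1a1 changed by -0.30 ± 0.18 log2 (adjusted p = 0.744), Postn by -0.20 ± 0.24 (adjusted p = 0.912) and Mki67 by -0.073 ± 0.14 (adjusted p = 0.955). Targets of FGF and ERK signalling had log2 changes of -0.055 ± 0.16 for Dusp6, 0.13 ± 0.11 for Spry2, 0.23 ± 0.13 for Spry4 and -0.11 ± 0.10 for Etv5, and 0 of the 16 FGF feedback genes passed the threshold by limma (0 adjusted over the list alone, 2 at an unadjusted p under 0.05; median 0.10). The FGF feedback list had camera adjusted p = 0.0248, and adjusted p = 0.308 with an estimated correlation. In all, 28 of 12052 genes passed the threshold, 7 higher and 21 lower, and 1029 had an unadjusted p under 0.05. The count was 10 without MI day 3 control library 2 and also without control library 4, 15 without FGF17 library 3, 18 without FGF17 library 4, and 15 without both libraries of low mitochondrially encoded share. Of 16 named genes past the threshold, Fgf17, Apol11b, Car2 and Rsad2 stayed past it in every alternative run. The others lost the call in at least 1 alternative: 8 without control library 2, 9 without control library 4, 8 without FGF17 library 3, and 2 to 4 without each other library.

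The comparison of FGF17 with the control vector at day 14 after MI has the same limit (n = 3 and 3). Apart from Fgf17, 20 of 27 fatty acid oxidation genes rose, and 9 of 17 collagen, 18 of 27 other matrix and 16 of 27 cell cycle genes fell. With an estimated correlation these lists had adjusted p = 0.128, 0.215, 0.143 and 0.151. Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor (ENSMUSG00000032315.6, chromosome 9, 57687928 to 57703824, plus strand), rose from 1.20 ± 0.698 to 15.9 ± 11.6 FPKM (log2 change 3.15 ± 0.43, adjusted p = 0.00128). Acot2 rose from 15.0 ± 2.27 to 36.4 ± 2.83 FPKM (adjusted p = 5.74e-04). Inmt, Pja1, Acadsb and Myh7b rose by log2 changes of 1.62 ± 0.43, 1.45 ± 0.31, 1.32 ± 0.36 and 1.19 ± 0.27. Postn fell from 146 ± 38.7 to 57.9 ± 21.6 FPKM (-1.36 ± 0.28 log2, adjusted p = 0.00782), Lox, the collagen crosslinking lysyl oxidase, from 59.3 ± 18.8 to 20.7 ± 5.54 FPKM (adjusted p = 0.00227), Col8a1 from 90.1 ± 27.1 to 27.6 ± 9.94 FPKM and C1qtnf3 from 18.8 ± 3.01 to 5.30 ± 2.72 FPKM. Adamts8, Trp53i11, Mest and the vasoactive peptide gene Uts2b fell, with log2 changes of -1.76 ± 0.45, -1.68 ± 0.35, -1.59 ± 0.21 and -1.98 ± 0.56. Ccna2, the S phase cyclin A2 (ENSMUSG00000027715.9, chromosome 3, 36564865 to 36572150, minus strand), fell from 3.02 ± 1.03 to 1.02 ± 0.0419 FPKM (adjusted p = 0.00115), and Nppa from 3083 ± 505 to 1746 ± 197 FPKM (adjusted p = 0.0147), where sham had 1656 ± 306 FPKM. The Nppa call was lost with only these 6 libraries fitted, with the library number as a block and without MI day 14 control library 1 or 2. Of 9 atrial markers 1 fell (3 adjusted over the list alone, and 2 over all genes without both libraries of low mitochondrially encoded share; median -0.35 log2, camera adjusted p = 0.108).

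With FGF17 at day 14, 20 of 27 fatty acid oxidation genes rose (23 higher and 1 lower adjusted over the list alone), by a median of 0.52 log2, with 0.56 ± 0.093 for Acadm, 0.64 ± 0.10 for Decr1, 0.62 ± 0.10 for Etfdh and 0.54 ± 0.16 for Cpt1b. The fatty acid oxidation list had camera adjusted p = 4.35e-18, and adjusted p = 0.128 with an estimated correlation. Of 20 tricarboxylic acid cycle genes 11 rose (16 adjusted over the list alone), with 0.51 ± 0.093 log2 for Sdha, and of 36 complex I genes 6 (10 adjusted over the list alone), with 0.68 ± 0.15 for Ndufv1. The tricarboxylic acid cycle list had camera adjusted p = 1.27e-11, and adjusted p = 0.143 with an estimated correlation. The complex I list had camera adjusted p = 1.66e-08, and adjusted p = 0.215 with an estimated correlation. Of 31 genes of complexes III, IV and ATP synthase 2 rose (5 adjusted over the list alone, and 4 over all genes with median-of-ratios scaling). The complex III, IV and ATP synthase list had camera adjusted p = 2.67e-07, and adjusted p = 0.215 with an estimated correlation. Of 18 mitochondrial biogenesis and dynamics genes 5 rose (5 adjusted over the list alone), with 0.83 ± 0.16 for the mitophagy kinase gene Pink1. The mitochondrial biogenesis list had camera adjusted p = 3.37e-04, and adjusted p = 0.0644 with an estimated correlation. The mitochondrially encoded genes had a median of -0.29 log2 (camera adjusted p = 0.191), with 0 of 13 past the threshold by limma, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05. Sarcomere genes rose in 4 of 18 cases (7 adjusted over the list alone), with 0.61 ± 0.16 for Myh6 and 0.43 ± 0.10 for Tnnt2, and calcium handling genes in 6 of 20 (9 adjusted over the list alone), with 0.46 ± 0.11 for Atp2a2. The sarcomere list had camera adjusted p = 5.04e-06, and adjusted p = 0.215 with an estimated correlation. The calcium handling list had camera adjusted p = 1.31e-06, and adjusted p = 0.183 with an estimated correlation.

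Of 17 collagen genes 9 fell (15 adjusted over the list alone), by a median of -0.62 log2, with -1.33 ± 0.19 for Col11a1, while Col1a1 and Col3a1 had -0.62 ± 0.21 and -0.62 ± 0.21 (adjusted p = 0.0713 and 0.0673). The collagen list had camera adjusted p = 1.39e-09, and adjusted p = 0.215 with an estimated correlation. Of 27 other matrix genes 18 fell (23 adjusted over the list alone), by a median of -0.99 log2, with -1.04 ± 0.26 for Timp1. The other matrix list had camera adjusted p = 2.61e-14, and adjusted p = 0.143 with an estimated correlation. Cell cycle genes fell in 16 of 27 cases (21 adjusted over the list alone), with -1.07 ± 0.17 log2 for Mki67. The cell cycle list had camera adjusted p = 1.21e-13, and adjusted p = 0.151 with an estimated correlation. TGF-beta and myofibroblast genes fell in 6 of 18 cases (10 adjusted over the list alone). The TGF-beta and myofibroblast list had camera adjusted p = 7.24e-05, and adjusted p = 0.215 with an estimated correlation. Macrophage markers fell in 4 of 19 cases (10 adjusted over the list alone), with -0.67 ± 0.17 for Ms4a7. The macrophage list had camera adjusted p = 6.25e-04, and adjusted p = 0.284 with an estimated correlation. Fibroblast markers rose in 1 and fell in 5 of 14 cases (2 and 8 adjusted over the list alone), with -0.69 ± 0.13 for Fap, and endothelial markers fell in 2 of 15 (2 adjusted over the list alone), with -0.48 ± 0.10 for Cdh5. The fibroblast list had camera adjusted p = 0.00203, and adjusted p = 0.215 with an estimated correlation. The endothelial list had camera adjusted p = 0.0226, and adjusted p = 0.367 with an estimated correlation. Of 20 interferon-stimulated genes 1 fell (1 adjusted over the list alone), with a median of -0.28 log2, and limma called 0 without both libraries of low mitochondrially encoded share (1 lower at an unadjusted p under 0.05). The interferon-stimulated list had camera adjusted p = 0.0214, and adjusted p = 0.572 with an estimated correlation. The peptide gene Apln and its receptor gene Aplnr fell, with log2 changes of -1.29 ± 0.25 and -0.95 ± 0.17. Of 7 skeletal muscle markers 4 fell (4 adjusted over the list alone), among them the fast muscle genes Tnnt3, Tnnc2 and Mylpf with -2.60 ± 0.57, -2.18 ± 0.31 and -1.77 ± 0.27 log2. The skeletal muscle list had camera adjusted p = 6.47e-04, and adjusted p = 0.0644 with an estimated correlation. Its mean log2 value was 1.40 in sham, 1.55 in MI day 14 with FGF17 and 2.76 in the MI day 14 controls. The controls were thus the group apart, for a reason that was not tested.

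FGF feedback genes fell in 2 and rose in 0 of 16 cases at day 14 (2 and 0 adjusted over the list alone, 2 and 1 at an unadjusted p under 0.05, camera adjusted p = 0.348). Etv5, a transcription factor downstream of FGF receptors (ENSMUSG00000013089.15, chromosome 16, 22381309 to 22439719, minus strand), changed by -0.43 ± 0.12 log2 (adjusted p = 0.0312), Dusp6 by -0.36 ± 0.18 (adjusted p = 0.224), Spry2 by 0.24 ± 0.12 (adjusted p = 0.232) and Spry4 by -0.17 ± 0.14 (adjusted p = 0.480). The Etv5 call was lost after rescaling, with only these 6 libraries fitted, with the library number as a block, and without control library 1 or 2 or FGF17 library 1 or 3. In all, 1159 genes passed the threshold, 438 higher and 721 lower, against 610 higher and 665 lower with median-of-ratios scaling and 422 and 386 after rescaling to 1000000. The count was 104 when only the 6 libraries compared were fitted, with 3 fatty acid oxidation genes higher and 1 lower, and 2 collagen, 2 other matrix and 2 cell cycle genes lower. Of tricarboxylic acid cycle, complex I, sarcomere and calcium handling genes, limma called 0 in that fit, with 14, 11, 6 and 9 higher at an unadjusted p under 0.05. Of TGF-beta, macrophage and fibroblast genes it also called 0, with 9, 10 and 6 lower at an unadjusted p under 0.05. Without both libraries of low mitochondrially encoded share, 15 collagen genes and 1 macrophage marker fell, and 1 sarcomere and 3 calcium handling genes rose. The count of genes was 229 without MI day 14 control library 1, 392 without control library 2 and 378 without FGF17 library 3. Of 39 named genes past the threshold, 15 stayed past it in every alternative run, among them Fgf17, Cyp1a1, Acot2, Lox, Col8a1, Col11a1, Ccna2, Apln and Pink1. The call was lost by 20 with only these 6 libraries fitted, 18 without control library 1, 12 without control library 2, 10 without FGF17 library 3, 6 without FGF17 library 4 and 5 without FGF17 library 1.

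**Figure D2:**
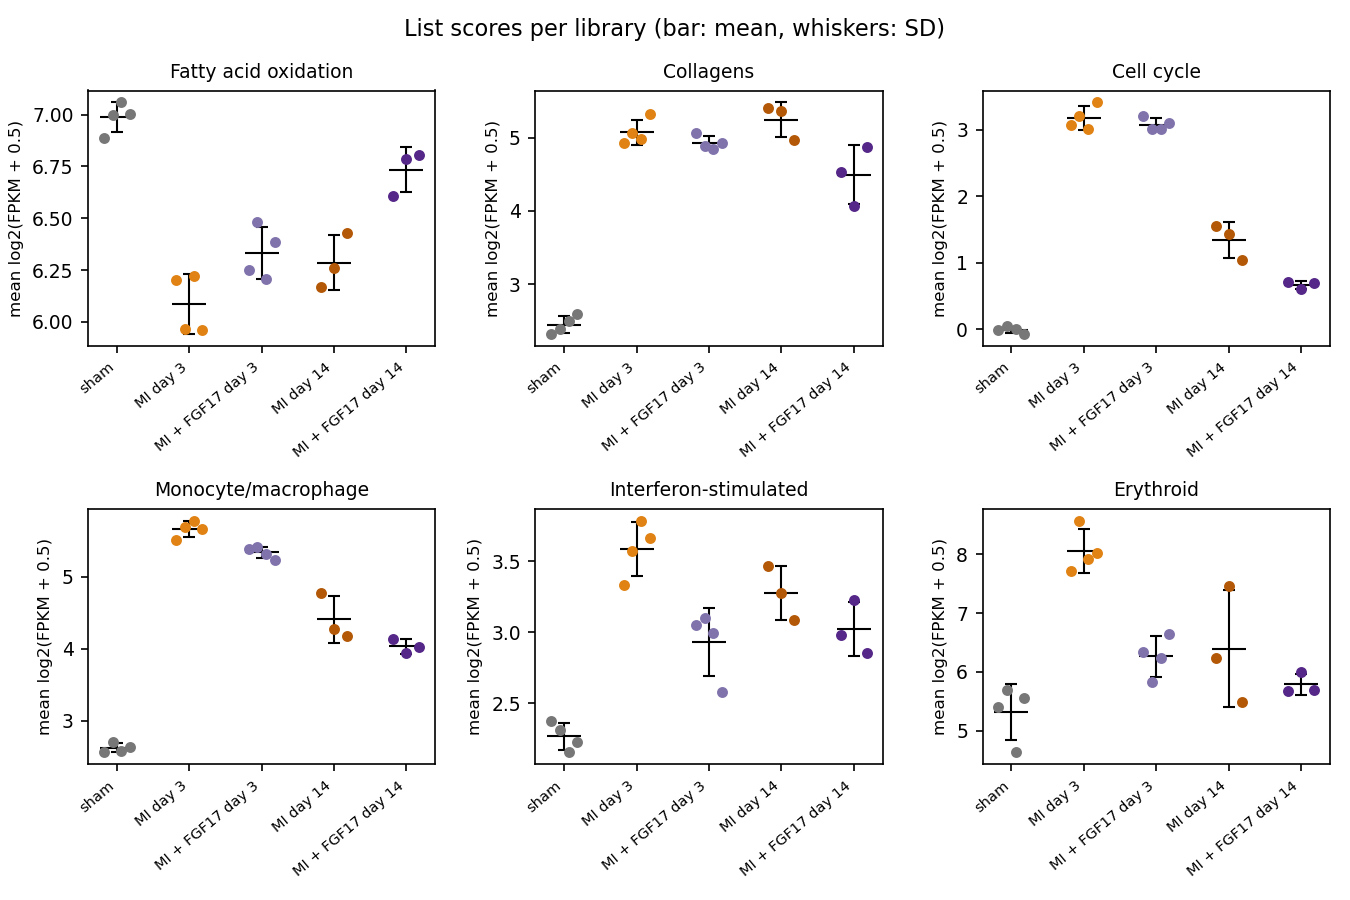
Each point is the mean log2(FPKM + 0.5) over the genes of a list in 1 library, bars are group means and whiskers SD, with 1 panel per list and the 5 groups along the horizontal axis. All 4 FGF17 libraries at day 3 lie below all MI day 3 control libraries for interferon-stimulated and erythroid genes, and above all sham libraries. All 3 FGF17 libraries at day 14 lie above all MI day 14 control libraries for fatty acid oxidation and below them for collagens, and lie between these and all sham libraries.

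**Figure D3:**
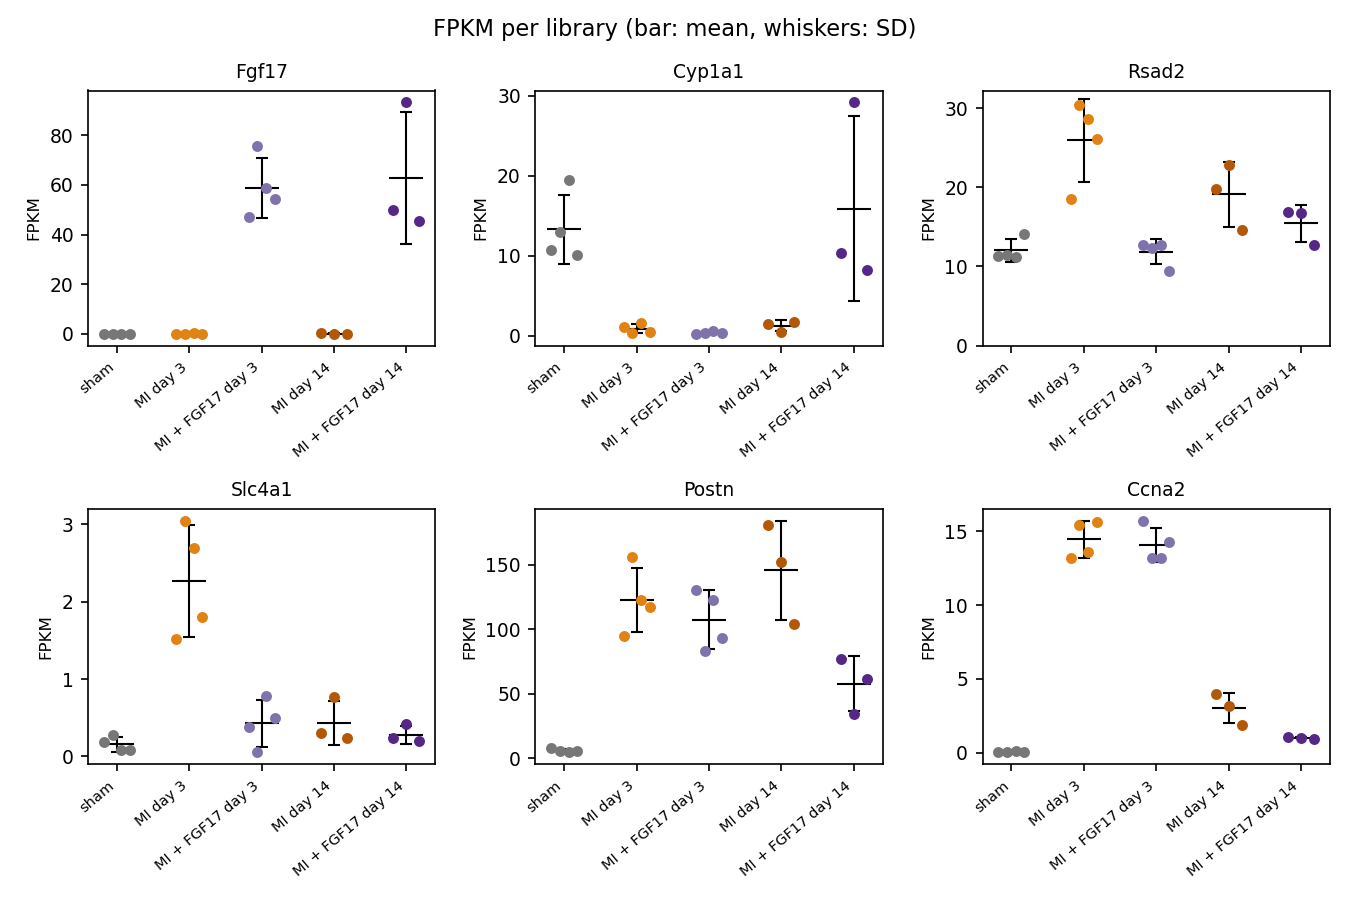
FPKM per library (points), group mean (bar) and SD (whiskers) of Fgf17, Cyp1a1, Rsad2, Slc4a1, Postn and Ccna2 in the 5 groups. Postn has means of 146 and 57.9 FPKM in the control and FGF17 groups at day 14, and Rsad2 of 25.9 and 11.8 FPKM at day 3.

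The next question was whether genes differed with FGF17 in the direction opposite to MI. Without a sham group with the Fgf17 vector, such differences may have been present before MI. Contrasts that share no library were correlated across genes other than Fgf17, with the caution that genes are not independent replicates. The FGF17 effect at day 14 and the MI effect at day 3 had Pearson's r = -0.599 and Spearman's rho = -0.633 over 12051 genes. The jackknife SE of r was 0.0849 over the FGF17 and control libraries of day 14. It leaves out the spread of the sham and MI day 3 libraries. Another split of the day 14 libraries gave an r of 0.587 in size, and the 10 splits are too few to exclude chance. Of the genes past both thresholds, 372 were higher with FGF17 at day 14 and lower in MI at day 3, where independence gives 65.5, and 649 were lower with FGF17 and higher in MI, where it gives 331. The same direction held for 5 genes higher in both and 8 lower in both, where independence gives 201 and 108. The FGF17 effect at day 3 and the MI effect at day 14 had r = -0.277 (jackknife SE 0.0619 over the day 3 libraries only) and rho = -0.307. Here 3 of 35 splits, the real one included, gave a correlation as far from 0, so chance cannot be excluded. Of the 21 genes lower with FGF17 at day 3, 15 were higher in MI at day 14, where independence gives 8.61. Contrasts of the same day share the MI control libraries, which alone makes them correlate. At day 14, r was -0.782 against -0.532 in simulated groups with no effect, and at day 3 -0.418 against -0.502. The simulated groups had no MI effect either, so these values of r cannot be compared in size. The covariance was -0.152 against -0.0216 simulated at day 14, and -0.0727 against -0.0163 at day 3. With the day 3 controls split between the contrasts, 2 libraries in each, r was -0.266 (range -0.323 to -0.175).

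Whether the FGF17 effect differed between the days was tested by the difference of the effects, day 14 minus day 3. Fgf17 itself had effects of 6.57 and 6.71 log2 at day 3 and day 14. Cyp1a1 had an FGF17 effect of -0.64 log2 at day 3 and 3.15 at day 14, and the difference was 3.79 ± 0.57 log2 (adjusted p = 0.0265). Apol11b and H2-Q6, lower with FGF17 at day 3, had differences of 2.77 ± 0.56 and 1.77 ± 0.31 log2, and Trim54, Fam220a, Psmc3 and Stk40 of 0.91 ± 0.18, 0.77 ± 0.15, 0.68 ± 0.13 and 0.68 ± 0.14. Negative differences were found for the matrix proteoglycan genes Lum with -1.14 ± 0.22 (adjusted p = 0.0433) and Prelp with -1.16 ± 0.22, for Nrep with -1.37 ± 0.21, Ptn with -1.36 ± 0.27, Naalad2 with -1.14 ± 0.23 and C1qtnf3 with -1.71 ± 0.35, and for the cell cycle genes Ccna2 with -1.13 ± 0.21 (adjusted p = 0.0324) and Cdca3 with -1.22 ± 0.20. Postn and Mki67 (adjusted p = 0.161 and 0.0596) did not pass, nor did Timp1, Nppa and Ppargc1a, with differences of -0.88 ± 0.35, -0.68 ± 0.25 and -1.03 ± 0.39 (adjusted p = 0.261, 0.222 and 0.236).

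Matrix genes had a median difference of -0.83 log2 with 1 of 27 lower over all genes and 17 adjusted over the list alone, and cell cycle genes of -0.55 with 3 of 27 and 12 adjusted over the list alone (camera adjusted p = 5.32e-13 and 3.12e-12). With an estimated correlation, each had adjusted p = 0.336. Fatty acid oxidation genes had a median difference of 0.35 log2, with 0 of 27 past the threshold by limma and 10 higher and 1 lower adjusted over the list alone, and 15 and 2 at an unadjusted p under 0.05. The fatty acid oxidation list had camera adjusted p = 8.83e-08, and adjusted p = 0.336 with an estimated correlation. Skeletal muscle markers had 1 of 7 lower (4 adjusted over the list alone), and the 3 MI day 14 control libraries alone had high values of this list. The skeletal muscle list had camera adjusted p = 1.91e-04, and adjusted p = 0.0388 with an estimated correlation. In all, 44 genes passed, 13 with a positive and 31 with a negative difference, against 15 and 89 with mitochondrially encoded genes left out before rescaling. The limma count was 0 without MI day 3 control library 1, MI day 3 FGF17 library 4, MI day 14 control library 2 or MI day 14 FGF17 library 3, with 1476, 1584, 1449 and 1424 genes at an unadjusted p under 0.05, and it was 3 without MI day 14 control library 1, 7 and 15 without MI day 3 FGF17 libraries 3 and 1, 27 and 81 without MI day 14 FGF17 libraries 4 and 1, and 193 without MI day 14 control library 4. No named gene past the threshold stayed past it in every alternative run.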

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

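Of the tests in this part, those of scaling, single libraries, tissue share and red cell RNA were chosen only after the results were seen, and the counts of other splits were planned.

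With FGF17 at day 14, 9 of 17 collagen genes fell and 20 of 27 fatty acid oxidation genes rose (2 and 3 with only these 6 libraries fitted; adjusted p = 0.215 and 0.128 for the lists with an estimated correlation), and their mean log2 values differed by -0.75 (SE 0.27) and 0.45 (SE 0.099). The tables argue against the scaling between libraries as the whole cause, since 96.8% of the change was left with median-of-ratios factors, and against 1 library, since at least 71.8% was left without any 1 library (the lowest, for collagens without MI day 14 FGF17 library 3). A different share of infarcted tissue in the FGF17 libraries cannot be told apart: the share of the MI change that was undone differed from that of the macrophage list by 0.0216 (SE 0.116) for collagens and 0.143 (SE 0.125) for fatty acid oxidation, errors too large to decide. Outside this pattern, the cell cycle list differed by 0.221 (SE 0.101) and complex I by 0.251 (SE 0.163). An effect of FGF17 on the scar or on the surviving muscle may also account for it and was not tested apart from this. A difference present before MI cannot be told apart either.

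With FGF17 at day 3, 5 of 20 interferon-stimulated genes fell (adjusted p = 0.0551 for the list with an estimated correlation), and the mean log2 value of the list differed by -0.65 (SE 0.15). The tables argue against scaling, with 95.6% of the change left, and against 1 library, with at least 82.0% left (without MI day 3 FGF17 library 4). They also argue against a smaller share of infarcted tissue as the whole cause, since the share of the MI change undone was larger than that of the macrophage list by 0.414 (SE 0.0915). An effect of FGF17 on interferon signalling may account for it, as a hypothesis found and tested on the same data. A difference between the animals' exposure to virus or vector was not tested, and a difference present before MI cannot be told apart.

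With FGF17 at day 3, 2 of 8 erythroid genes fell (adjusted p = 0.0551 for the list with an estimated correlation), and the mean log2 value of the list differed by -1.79 (SE 0.25). Scaling left 98.1% of the change and leaving out 1 library at least 90.4% (without MI day 3 control library 2), which argues against both. Less red blood cell RNA in the FGF17 hearts, from blood left in the tissue or bleeding into the infarct, may account for it. The 4 globin genes had a median of -1.58 log2, which is 76.6% of the -2.07 log2 of the 4 other members, so abundant and scarce erythroid transcripts were lower together. All 8 members were already known to be lower adjusted over the list alone, so this comparison could hardly come out otherwise. Hbb-bs stood at 7619 and 2365 FPKM in the control and FGF17 groups. Whether this comes from the collection of the hearts or from FGF17 was not tested.

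Other splits of the same libraries were refitted to ask whether chance can be excluded. For the genes of MI day 3 against sham, 1 of 35 splits, the real one, gave as many (7337, highest other 1). The same share held for MI day 14 against sham (6025, highest other 2911) and MI day 14 against day 3 (3555, highest other 1583). It also held for FGF17 at day 3 (28, highest other 1). This share is under 0.05, but it is the smallest that 35 splits allow and was not adjusted over contrasts. A split that mixes the 2 groups adds their difference to the spread, which can lower its count. These counts therefore do not exclude chance by themselves. For FGF17 at day 14, 10 splits are too few for a share under 0.05 (1 split gave as many, 1159 genes, highest other 1). For the difference between the days chance cannot be excluded: 5 of 100 splits gave as many as the 44 genes, and the highest other gave 227. The splits were drawn from all combinations of splits at the 2 days other than the real one. Some combinations keep the FGF17 grouping of 1 day, and so its effect. The count of 227 therefore need not come from another structure of the samples, which was not tested. For the gene lists of MI day 3 against sham, 1 of 35 splits, the real one, gave as many (24 lists). The highest other split gave 23. A margin of 1 list hardly sets the real split apart, so no conclusion is drawn from this count. Chance cannot be excluded for the lists of MI day 14 against sham (13 of 35, 20 lists, highest other 22), FGF17 at day 3 (7 of 35, 15 lists, highest other 18), MI day 14 against day 3 (4 of 35, 21 lists, highest other 23) and the difference between the days (17 of 100, 18 lists, highest other 22). For the lists of FGF17 at day 14 the 10 splits are too few (1 split gave as many, 20 lists, highest other 19). They are also too few for the correlation between FGF17 at day 14 and MI (1 split as far from 0, -0.599, highest other 0.587). For FGF17 at day 3, 3 of 35 splits gave a correlation as far from 0 (-0.277, highest other 0.305), and chance cannot be excluded.

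Single libraries lay far from the others of their group of 4 in 37 of 447 such tests over genes, gene lists and library measures, where chance gives about 1 in 20, or 22.4. Sham library 2 had Spp1 at 4.08 FPKM (others 1.78 to 2.05), Sfrp2 at 1.69 FPKM (others 2.13 to 2.16) and Tnnc2 at 0.165 FPKM (others 0). Sham library 2 also had Ccl7 at 5.30 FPKM (others 9.68 to 9.89), Ccl2 at 4.94 FPKM (others 7.28 to 7.49) and Trim54 at 222 FPKM (others 205.6 to 206.4). MI day 3 control library 2 had Sprr1a at 181 FPKM (others 122 to 131), Mki67 at 13.6 FPKM (others 11.2 to 11.4) and Acot1 at 1.73 FPKM (others 1.27 to 1.34). MI day 3 control library 2 also had Bpgm at 77.3 FPKM (others 41.3 to 45.8), Tnnt3 at 14.6 FPKM (others 1.95 to 2.74) and Tnnc2 at 0.346 FPKM (others 0). MI day 3 FGF17 library 2 had Saa3 at 168 FPKM (others 15.8 to 24.8), Lgals4 at 8.61 FPKM (others 3.45 to 4.02) and Pnpla2 at 61.0 FPKM (others 39.2 to 41.9). MI day 3 FGF17 library 2 also had H2-Q6 at 13.8 FPKM (others 7.79 to 8.75) and Trim54 at 87.1 FPKM (others 68.9 to 72.0). MI day 3 FGF17 library 3 had Cyp1a1 at 0.504 FPKM (others 0.237 to 0.280), C1qtnf3 at 0.527 FPKM (others 0.0895 to 0.138) and Tmem100 at 34.8 FPKM (others 25.5 to 26.8). MI day 3 FGF17 library 3 also had Ptn at 11.2 FPKM (others 8.86 to 9.07). MI day 3 control library 4 had a mitochondrially encoded share of 18.8% (others 28.1 to 28.4%), a mean log2 value over the glycolysis list of 6.30 (others 6.16 to 6.17) and Col1a1 at 409 FPKM (others 234 to 261). Sham library 5 had C1qtnf3 at 0.0487 FPKM (others 0), Emp1 at 18.6 FPKM (others 1.70 to 2.76) and Rsad2 at 14.2 FPKM (others 11.1 to 11.5). MI day 3 control library 3 had Mid1ip1 at 51.4 FPKM (others 10.6 to 12.4), Fmod at 1.12 FPKM (others 2.55 to 2.80) and S100a9 at 175 FPKM (others 85.0 to 99.8). MI day 3 FGF17 library 4 had Isg15 at 16.98 FPKM (others 24.0 to 25.4), Rsad2 at 9.49 FPKM (others 12.4 to 12.7) and Ifi44 at 1.36 FPKM (others 2.22 to 2.29). MI day 3 control library 1 had a mean log2 value over the mitochondrial biogenesis and dynamics list of 3.91 (others 3.76 to 3.79). Sham library 1 had Cthrc1 at 0.518 FPKM (others 0.0789 to 0.122). MI day 3 FGF17 library 1 had Ltbp2 at 8.06 FPKM (others 6.29 to 6.53). Sham library 4 had Hbb-bs at 689 FPKM (others 1397 to 1541).

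Of the 44 genes past the threshold in the test of the difference (day 14 minus day 3, log2), 18 of those that the fixed rule names are given here, although chance cannot be excluded for the count of 44. None kept the call in every alternative, and limma called 0 genes with the library number as a block and without any of 4 single libraries. The difference was positive for Cyp1a1 (3.79), Apol11b (2.77), H2-Q6 (1.77), Cpeb3 (1.168), Trim54 (0.91), Fam220a (0.77), Psmc3 (0.68) and Stk40 (0.68). It was negative for C1qtnf3 (-1.71), Ccna2 (-1.13), Tnnc2 (-2.25), Fap (-0.86), Nrep (-1.37), Ptn (-1.36), Cdca3 (-1.22), Prelp (-1.16), Naalad2 (-1.14) and Lum (-1.14). Among gene lists called by camera, the median difference was positive for sarcomere (0.14), calcium handling (0.35), fatty acid oxidation (0.35), tricarboxylic acid cycle (0.19), complex I (0.086), interferon-stimulated (0.33), unfolded protein response (0.14) and erythroid (1.09) genes and negative for cardiac stress (-0.35), collagen (-0.53), other matrix (-0.83), TGF-beta and myofibroblast (-0.29), cell cycle (-0.55), FGF feedback (-0.27), mitochondrially encoded (-0.42), fibroblast (-0.43), endothelial (-0.24) and skeletal muscle (-0.85) genes, and with an estimated correlation only the skeletal muscle list stayed past the threshold. Interferon-stimulated genes had medians of the same sign at day 3 and day 14, -0.59 and -0.28 log2.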

How the results depend on the processing

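The tests with mitochondrially encoded genes left out and with both libraries of low mitochondrially encoded share left out were chosen after the data were seen; all other alternatives were planned and run. Over the counts of genes and lists, the correlations and the Fgf17 level, 140 alternatives were labelled the same. A smaller count came from 33, a larger one from 4, and 1 moved a correlation. A count was labelled the same within a fixed ratio of the main count, whatever its split into higher and lower. A correlation was labelled the same within its jackknife SE. For FGF17 at day 14, 808 genes after rescaling against 1159 in the main run were still labelled the same. For named genes, 3308 values kept direction and side of the threshold, 359 kept direction and lost the call, 32 gained it and 35 changed direction. For gene lists, 351 kept both, 136 lost the call, 10 gained it and 7 changed direction. No named gene past the threshold changed direction.

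A filter at 5 FPKM, which tests fewer genes, gave 4645 genes for MI day 3 against sham, 3715 for MI day 14 against sham and 18 for FGF17 at day 3. A fit of only the groups compared gave 104 genes for FGF17 at day 14 and 10 for the difference between the days. It has fewer samples to estimate the spread and uses the spread of those groups alone, which can differ. The mean log2 value of the other matrix list had SD 0.251 and 0.441 in MI day 14 control and FGF17. In sham, MI day 3 control and MI day 3 FGF17, the SD was 0.0976, 0.0766 and 0.0401. For fatty acid oxidation the values, in the same order, were 0.132, 0.108, 0.0733, 0.145 and 0.126. The reason for the lower counts was not tested. With the library number as a block, 700 genes passed for FGF17 at day 14 and 0 for the difference between the days (1665 at an unadjusted p under 0.05). Libraries of the same number showed no general pairing, with a median r of 29 pairs of residuals of 0.0146 (range -0.155 to 0.366). Other pairs had a median of -0.00363 (range -0.318 to 0.226). The same number correlated best in 22 of 58 combinations of a library and another group. A pairing of some libraries is therefore not excluded. For the difference between the days, the count was 16 at a pseudocount of 0.1, 76 with median-of-ratios scaling, 17 after rescaling to 1000000 and 104 with mitochondrially encoded genes left out; the cause was not tested. Without both libraries of low mitochondrially encoded share, FGF17 at day 3 had 15 genes. Without 1 library, counts ranged from 6900 to 7043 for MI day 3, 4747 to 5849 for MI day 14, 10 to 36 for FGF17 at day 3, 229 to 1679 for FGF17 at day 14, 2604 to 3491 for day 14 against day 3 and 0 to 193 for the difference between the days. Without 1 of the day 14 libraries, the correlation of FGF17 at day 14 with MI ranged from -0.65 to -0.51, the weakest without MI day 14 control library 1. Sham and MI day 3 libraries were not left out for this correlation.

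Of 24, 20, 15, 20, 21 and 18 lists called by camera in the 6 contrasts, 1, 1, 0, 0, 1 and 1 passed with an estimated correlation, where 9, 13, 7, 7, 9 and 5 had an unadjusted p under 0.05, and 21, 18, 2, 19, 18 and 4 also passed by fry. Fry asks if a list moves 1 way, not if it moves further than other genes. The median of a list and the direction of camera differed in sign for 8, 8, 4, 2, 2 and 2 of 37 lists, and the mean for 8, 8, 4, 2, 2 and 0. Camera compares with the other genes, which accounts for only some of these. Relative to the median of all genes, list medians still differed in sign for 2, 4, 2, 2, 1 and 1 lists. Among lists called, the plain median or mean differed in sign from camera only for antioxidant genes in MI day 3. These were lower by camera (adjusted p = 0.0204) with a median of -0.15 and a mean of 0.13 log2. The camera call was lost with an estimated correlation (adjusted p = 0.234) and with median-of-ratios scaling (adjusted p = 0.0526). The signs changed for lists that camera did not call: unfolded protein response genes in MI day 3 (fry adjusted p = 2.68e-05, higher), neutrophil markers in MI day 14 (fry 0.257, median-of-ratios 0.544), atrial markers in MI day 14 (fry 0.0872), adipocyte markers in MI day 14 (fry 0.164, median-of-ratios 0.566) and neutrophil markers with FGF17 at day 14 (0.910 with the block).

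Genes not past the threshold that changed sign are given with log2 changes. Nppb, MI day 3 against sham, had -0.20 (median-of-ratios), -0.094 (mitochondrial genes out), -0.078 (both low libraries out) and -0.078 to 0.34 (without 1 library). Spry2, MI day 14 against sham, had -0.24 (median-of-ratios), -0.081 (mitochondrial genes out) and -0.077 to 0.10 (without 1 library). Nppb, MI day 14 against sham, had -0.14 (median-of-ratios) and -0.028 to 0.29 (without 1 library). S100a8, FGF17 at day 3 after MI, had -0.24 to 0.46 (without 1 library). Nppb, FGF17 at day 3 after MI, had 0.020 (mitochondrial genes out), 0.12 (both low libraries out) and -0.30 to 0.12 (without 1 library). Hmox1, FGF17 at day 3 after MI, had -0.0053 (both low libraries out) and -0.0053 to 0.22 (without 1 library). Dusp6, FGF17 at day 3 after MI, had 0.024 (mitochondrial genes out) and -0.12 to 0.0080 (without 1 library). Mki67, FGF17 at day 3 after MI, had 0.0041 (mitochondrial genes out) and -0.14 to 0.037 (without 1 library). Nppb, FGF17 at day 14 after MI, had 0.063 (block) and -0.23 to 0.028 (without 1 library). S100a8, FGF17 at day 14 after MI, had -0.24 to 0.25 (without 1 library). Myh7, FGF17 at day 14 after MI, had -0.17 (both low libraries out) and -0.17 to 0.69 (without 1 library). The cause of these changes of sign was not tested. Depth is unknown, so no limit of detection is given for genes listed at 0.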

Other observations

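All list tests were planned, and the groups described here were chosen only after their results were seen. In MI day 3 against sham, p53 target and apoptosis genes rose in 13 of 17 cases (13 adjusted over the list alone), and in MI day 14 against sham in 13 of 17 (14 adjusted over the list alone). The p53 and apoptosis list at day 3 had camera adjusted p = 0.0246, and adjusted p = 0.211 with an estimated correlation. The p53 and apoptosis list at day 14 had camera adjusted p = 0.00749, and adjusted p = 0.103 with an estimated correlation. Angiogenic genes went both ways at day 3, with 11 higher and 5 lower of 19 (11 and 5 adjusted over the list alone, camera adjusted p = 0.750), and 13 higher and 2 lower at day 14 (14 and 3 adjusted over the list alone, camera adjusted p = 0.0860). T and NK cell markers rose in 6 of 6 cases at day 3 (6 adjusted over the list alone) and in 5 of 6 at day 14 (5 adjusted over the list alone, camera adjusted p = 0.314). The T and NK cell list had camera adjusted p = 0.0410, and adjusted p = 0.234 with an estimated correlation. Unfolded protein response genes at day 14 rose in 6 and fell in 9 of 21 cases (7 and 9 adjusted over the list alone). The unfolded protein response list had camera adjusted p = 0.00680, and adjusted p = 0.152 with an estimated correlation.

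Skeletal muscle markers had mean log2 values of 2.60 to 2.86 in the MI day 14 control libraries and 1.25 to 1.98 in all others, and every contrast with MI day 14 shares those controls. In MI day 14 against sham 5 of 7 rose (5 adjusted over the list alone, camera adjusted p = 0.197), and Tnnt3, of fast skeletal muscle troponin, had 0.565 ± 0.471 FPKM in sham, 6.15 ± 1.44 at MI day 14 with the control vector and 0.609 ± 0.335 with FGF17. Erythroid markers rose in 6 of 8 cases in MI day 14 against sham (7 adjusted over the list alone, camera adjusted p = 0.370), and with FGF17 at day 14 had a median of -0.71 log2, with 0 past the threshold by limma, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.108). Cardiac stress genes with FGF17 at day 14 fell in 2 of 11 cases (5 adjusted over the list alone). The cardiac stress list had camera adjusted p = 0.0104, and adjusted p = 0.302 with an estimated correlation. With FGF17 at day 3, camera called immediate-early genes of tissue handling higher by a median of 0.15 log2, with 0 past the threshold by limma and 1 adjusted over the list alone (2 at an unadjusted p under 0.05, adjusted p = 8.95e-04; adjusted p = 0.456 with an estimated correlation).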
